A study of Glycine max with 26 samples.

How the data were processed

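RNA of developing soybean seeds of cultivars OX951 and OX736 was measured on 26 spotted cDNA arrays of 19200 spots, in 48 print-tip blocks of 20 rows and 20 columns. The labels gave the stage (Early, Mid or Late), the biological replicate (1 to 4), the season (2004 or 2005) and the cultivar in each dye. Of the 26 arrays, 24 compared the cultivars, 8 per stage, and 2 were self-tests of a single cultivar. The dye-swapped arrays of a replicate held the same 2 RNA samples, so they were averaged and counted as 1 replicate, which left 12 pairs and 4 replicates per stage. The labels call the replicates biological.

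Per the file headers, the deposited scanner tables give for each spot and dye the intensity as a volume (mean pixel level times spot area), the local background and their difference, and the percent of pixels at the scanner's ceiling. The scan was not normalized between spots or arrays, per the file headers. The channel called control was read as Cy3 and the one called data as Cy5, from the channel order in the labels and from the averages in the deposited development table. The deposited series table holds log2 of Cy5 over Cy3 volume without background subtraction, scaling or centring, since each of 19200 rows equalled that value of 1 spot within 0.0001 on all arrays, and its array medians ran from -0.47 to 1.55. The authors' deposited cultivar table holds a ratio of OX736 over OX951 per clone and stage, normalized by intensity-dependent LOWESS in GeneSpring GX and merged over replicates, per the file headers. The authors' deposited development table holds mean background-subtracted volumes per stage and cultivar, not normalized.

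Volumes were turned into mean pixel levels by the spot area of 0.0064 square millimetres. The main setting was normexp background correction (offset 50), loess within print-tip blocks (span 0.3, 4 iterations) and, for intensities, quantile scaling of average intensities between arrays, in limma 3.58.1 under R 4.3.3. Blank spots (551 per array) had weight 0 in the loess and were left out after it. Spots of 1 clone were averaged (64 clones were spotted 4 times), which gave 18361 clones, and no spot carried a flag. Saturated spots were kept, and a channel was called saturated for a clone at 50 percent or more of pixels at the ceiling, and dim under 1.5 times background. Ratios were turned to OX736 over OX951 and averaged within each dye-swapped pair. For development the log2 intensities of both cultivars were averaged within each pair.

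Clones were named by the best database match in the deposited tables (18352 clones, 9 had none). The platform table gave 1 gene symbol for 1158 spots, several for 13, and did not list 18029. Accessions were shared for 1169 of 1171 spots, 1106 clones received a symbol, and 1153 gene numbers were found in the RefSeq table. Symbols were printed where they went with the description, or to state that they conflicted with it, and no genome position is given. Coordinates and near-identical gene copies were not analysed here, and a cDNA spot can bind transcripts of related genes.

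All stages were fitted together with limma, with moderated tests (lmFit and eBayes) and Benjamini-Hochberg adjustment at 0.05. The comparisons were the cultivar ratio at each stage and averaged over 3 stages, its change with stage (F test), its change with season with stage as a covariate, and the changes of intensity from Early to Mid and from Mid to Late. Whether equal replicate numbers pair the samples was checked. The tests, alternatives, 28 gene lists and the rule for named clones were fixed before the data were examined.

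The lists were search patterns on the match text, and were tested with camera at a preset correlation of 0.01 (lists of at least 5 clones) and with an estimated correlation. They covered cuticle, wax and cutin, lipid transfer, lignin and phenylpropanoids, flavonoids, isoflavonoids, class III peroxidases, cellulose and hemicellulose synthesis, xyloglucan, expansin and glucanase, pectin, structural wall proteins, BURP domain proteins, chitinases, storage and embryo proteins, seed maturation proteins and dehydrins, vegetative storage proteins and lipoxygenases, photosynthesis, ribosomal proteins, histones and cell division, proteases, sugar and starch, defence, heat shock, aquaporins, ABC transporters, auxin, gibberellin with abscisic acid and ethylene, redox enzymes and cytochromes P450. Storage proteins served as the marker of embryo and cotyledon, and photosynthesis as that of green tissue. The patterns also took in some unrelated matches, such as universal stress proteins in the BURP list, Gibberella proteins in the gibberellin list, bacterial pathogenesis proteins in the defence list and trypsin inhibitor matches in the storage list.

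For each cultivar stage and each development comparison, the rule named the 6 largest rises and 6 largest falls past the threshold that had a descriptive match and the same sign in all 4 replicates, with 1 clone per description. It added up to 2 clones past the threshold per list, or the clone of smallest p as a value only, and, where none passed, the 6 clones of smallest p as values only.

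The procedure was tested on simulated data with 200 changed clones per comparison. At Late it recovered 43.3% of clones changed by a log2 of 0.5, 85.1% of those changed by 1 and 100% of those changed by 2, with 8 false calls. From Early to Mid it recovered 0 of 67 clones at 0.5, 22.4% at 1 and 86.4% at 2, and from Mid to Late 0 of 67, 17.9% and 78.8%. False calls were 13 at Early, 7 at Mid and 17 for the mean of the stages. The simulated noise was independent between clones and pairs, and each shift was equal in all replicates. Replicates of unlike quality or a shared season were not simulated, so these rates may not hold for the real arrays.

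Alternatives were plain background subtraction, a filter on dim clones, each replicate left out, the replicate number or the season as a block, each season alone, the deposited log2 values, a trended and robust fit, median centring without loess, each dye orientation alone, all 24 arrays with a correlation between partners, each stage alone, median scaling, each cultivar's channels alone, an estimated correlation and 1 value per description in the list tests. Fits without Mid replicate 3 and without Late replicate 4 were added after seeing the data. Tables were read with Python 3.11.15 (pandas 2.3.3, scipy 1.17.1) and figures drawn with matplotlib 3.10.9. Random draws used the seed 7.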

Results

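Gene expression in developing soybean seeds was compared between cultivar OX951, which has an impermeable seed coat, and cultivar OX736, which has a permeable seed coat. RNA of both cultivars was hybridised together to spotted cDNA arrays, 1 cultivar in the dye Cy3 and the other in Cy5. Early seeds were taken 10 to 20 days after pollination and gave RNA of the whole seed, while Mid (21 to 35 days) and Late (36 to 50 days) samples held the seed coat only. Each stage had 4 biological replicates, replicates 1 and 2 grown in 2004 and replicates 3 and 4 in 2005, and each replicate was hybridised to a pair of arrays with the dyes exchanged. The 24 cultivar arrays therefore gave 12 pairs, each averaged to 1 value (n = 4 per stage). A further 2 arrays, here called self-tests, carried RNA of a single cultivar in both dyes. All ratios are OX736 over OX951, so a positive log2 ratio means a higher level in OX736, and clones are named by their identifier with the best database match that the deposited tables give, which is often from another species.

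Each array measured 18361 clones, most of them as 1 spot. The median spot level per channel ranged from 1775 to 11710 scanner units over backgrounds of 384 to 3942, and 47.3% to 97.2% of the spots of an array reached 1.5 times background in at least 1 channel (median 94.1%). The dimmest pair was Mid replicate 3, with 51.8% of spots, and the widest spread of log2 ratios was that of Late replicate 4 (SD 0.67 across clones). Across clones, which are not independent replicates, the turned log2 ratios of dye-swapped partners correlated at 0.40 to 0.86 in replicates 1, 3 and 4. In replicate 2 they correlated at 0.05 at Early, -0.16 at Mid and -0.03 at Late, so replicate 2 carried little cultivar difference that both dye orientations shared. The number of arrays limits the precision of every value.

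**Figure D1:**
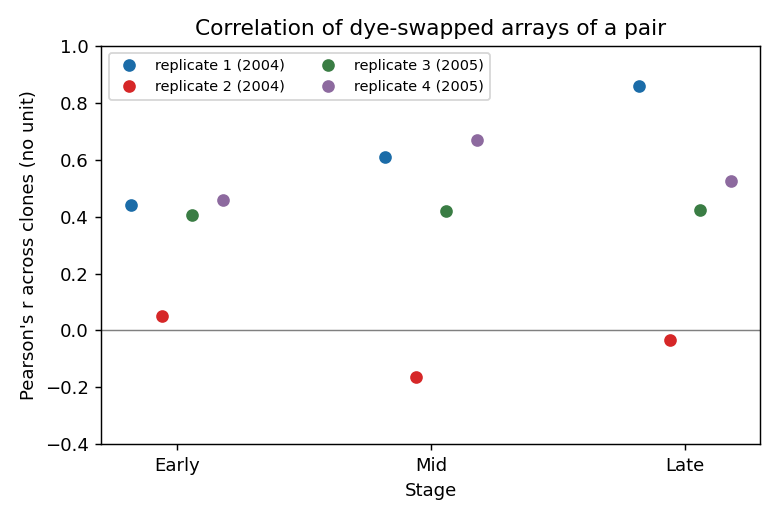
Correlation across clones of the log2 ratio OX736 over OX951 between the 2 dye-swapped arrays of each pair, by stage (x axis) and replicate (colour). The 3 pairs of replicate 2 lie between -0.16 and 0.05, and the other 9 between 0.40 and 0.86.

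At Early, when RNA came from the whole seed, 1 clone differed between the cultivars. A basic blue copper protein (Gm-r1021-2662), a member of a family of small copper-binding proteins, was 1.63-fold higher in OX736, at a log2 ratio of 0.70 (SE 0.0857, n = 4, limma adjusted p = 0.0419), and was higher in 4 of 4 replicates (0.64, 0.60, 0.83 and 0.74). It was the only one of 18361 clones past an adjusted p of 0.05, and 828 clones had an unadjusted p under 0.05. Its adjusted p was 0.0201 with season as a block, where 5 clones passed. Within 2004 its log2 ratio was 0.62 (adjusted p = 0.885) and 0 clones passed limma's threshold (769 at an unadjusted p under 0.05), and within 2005 it was 0.78 (0.444) and 2 passed. Without replicate 1, 2, 3 or 4 its adjusted p was 0.831, 0.574, 1.0 or 0.489, and 0 clones passed (686, 830, 442 and 941 at an unadjusted p under 0.05).

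Of the 28 gene lists, the photosynthesis list (chlorophyll-binding, photosystem and Rubisco clones) was higher in OX736 at Early by the camera test. Its 134 clones had a median log2 ratio of 0.08, 88 of them lay above 0, and the adjusted p was 1.13e-07, against an adjusted p of 0.247 with an estimated correlation. None of its members passed over all clones, and 4 rose when adjusted over the list alone. The list's adjusted p was 2.30e-07 with season as a block, 7.16e-07 within 2004 (median 0.10) 0.0107 within 2005 (median 0.06) and 0.0858 with OX736 in Cy5 only (median 0.03). Its member with the lowest p, a chlorophyll a/b-binding protein (Gm-r1083-1757), had a log2 ratio of 0.59 (SE 0.12, adjusted p = 0.444). The other 27 lists had adjusted p between 0.0793 and 0.918, the lowest for the vegetative storage protein and lipoxygenase list (median -0.10, 46 clones), which passed without replicate 1 (adjusted p = 0.0377), without replicate 2 (0.00125), within 2005 (median -0.13, 0.000175), with the deposited log2 values (0.0237) and with OX736 in Cy5 only (0.0105). Its medians per replicate were -0.02, 0.04, -0.19 and -0.15. In the flavonoid list 3 of 81 clones rose when adjusted over the list alone, and its flavonol synthase clone Gm-r1070-2559 had a log2 ratio of 0.62 (adjusted p = 0.546 over all clones).

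At Mid, in the seed coat, no clone passed limma's threshold (0 of 18361), and 1626 had an unadjusted p under 0.05. The 6 clones with the smallest p included a histone H4 (Gm-r1070-1500, log2 ratio 0.64, SE 0.101) and a MADS-box protein matching CAGL2 (Gm-r1070-7253, SEP1, -0.73, SE 0.115), each with an adjusted p of 0.147. With season as a block both passed, at adjusted p of 0.0455 and 0.0319. An F-box-like protein (Gm-r1070-597) had -0.62 and a helicase-like protein (Gm-r1021-1214) -0.51, at adjusted p of 0.370 and 0.390. UDP-glucose dehydrogenase (Gm-r1070-5804, UGD1), which makes a precursor of wall polysaccharides, had -0.85 (SE 0.208, adjusted p = 0.412), and isoflavone synthase (Gm-r1021-2091, IFS1) had 0.39 (adjusted p = 0.412). The season as a block gave 16 clones past the threshold, within 2004 there were 0 (1143 at an unadjusted p under 0.05) and within 2005 there was 1. Leaving out any 1 replicate left the count at 0, with 1384, 1222, 851 and 1860 clones at an unadjusted p under 0.05 without replicates 1, 2, 3 and 4.

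Gene lists moved at Mid without single clones passing. Clones of ribosomal proteins, the protein part of the translation machinery, were higher in OX736 (median 0.08, 340 of 486 above 0, adjusted p = 1.81e-06, or 0.286 with an estimated correlation). The photosynthesis list was higher as well (median 0.09, 93 of 134 above 0, adjusted p = 0.00858, or 0.592 with an estimated correlation). The list of histone, cyclin and tubulin clones was higher too (median 0.04, 105 of 182 above 0, adjusted p = 0.0257, or 0.399 with an estimated correlation), and 5 of its members rose when adjusted over the list alone. With season as a block the adjusted p were 7.84e-07, 0.00872 and 0.0337. The ribosomal list had medians of 0.04 within 2004 (0.307) and 0.12 within 2005 (1.47e-07), the photosynthesis list 0.13 (0.000420) and 0.01 (0.798), and the histone list 0.03 (0.307) and 0.06 (0.0497). Without replicate 1 the photosynthesis list had an adjusted p of 0.167, and without replicate 3 the histone list had 0.307, while without replicate 2 the storage protein and embryo list passed as well, lower in OX736 (median -0.11, adjusted p = 0.0273), as it did within 2005 (median -0.11, 0.0117). With the deposited log2 values all 3 calls were lost (ribosomal 0.0854, photosynthesis 0.0637, histone 0.222). The photosynthesis list was also lost with OX736 in Cy5 only (0.400), and the histone list with 1 value per description (0.424), without Mid replicate 3 (0.229) and with OX736 in Cy5 or in Cy3 only (0.128, 0.204). The remaining 25 lists had adjusted p from 0.275 to 0.998.

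At Late, 48 clones differed between the cultivars, and 43 of them were lower in the permeable-coat cultivar OX736. The seed maturation protein PM41 (Gm-r1070-536) was 2.69-fold lower (log2 ratio -1.43, SE 0.130, adjusted p = 0.000983), and a dehydrin (Gm-r1070-1738), of a family that accumulates in drying seeds, was 2.23-fold lower (-1.16, SE 0.193, 0.0318). A putative imbibition protein (Gm-r1083-2642) was 3.37-fold lower (-1.75, SE 0.264, 0.0182) and a wound-induced protein (Gm-r1070-2232, WIN) 2.43-fold lower (-1.28, SE 0.180, 0.0119). A lipid transfer protein (Gm-r1070-3025) was 1.84-fold lower (-0.88, SE 0.12, 0.0101), a proline-rich APG isolog (Gm-r1070-4457) 2.04-fold lower (-1.03, SE 0.188, 0.0463), and beta-xylosidases, which remove xylose from wall polysaccharides, were lower by 1.68-fold (Gm-r1021-1255) and 1.45-fold (Gm-r1021-2070). In the other direction a nodule-enhanced malate dehydrogenase (Gm-r1070-1784) was 1.53-fold higher (0.62, SE 0.0979, 0.0256) and a DNA-binding protein (Gm-r1070-5931) 1.48-fold higher (0.56, SE 0.103, 0.0492).

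In all, 48 of 18361 clones passed limma's threshold at Late, 5 higher and 43 lower in OX736, and 2411 had an unadjusted p under 0.05. Clones without a descriptive match, which the rule left out, included larger falls than some named here. Among clones with such a match, further falls were those of a dehydrogenase (Gm-r1070-8178, 2.99-fold), a Prp8-like splicing factor (Gm-r1070-7746, 2.82-fold) and a retroelement reverse transcriptase (Gm-r1083-930, 2.5-fold), to which the platform table gives another gene, HIDH. The other 3 higher clones, with no descriptive match and named after their values were seen, were Gm-r1070-413 (0.74), Gm-r1070-8698 (0.54) and Gm-r1083-3417 (0.67). Also singled out after their values were seen were the seed maturation protein PM39 (Gm-r1070-8130, -0.93, adjusted p = 0.0119), GDP-mannose dehydratase (Gm-r1070-4486, -1.21, 0.00585), an acetyl-CoA carboxylase (Gm-r1070-1667, -0.68, 0.00701) and an omega-6 desaturase (Gm-r1070-7656, -0.77, 0.0202). The identity of the carboxylase clone is unsettled, as the platform table gives it the symbol PM12, which it also gives to the dehydrin clone Gm-r1070-1738.

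**Figure D2:**
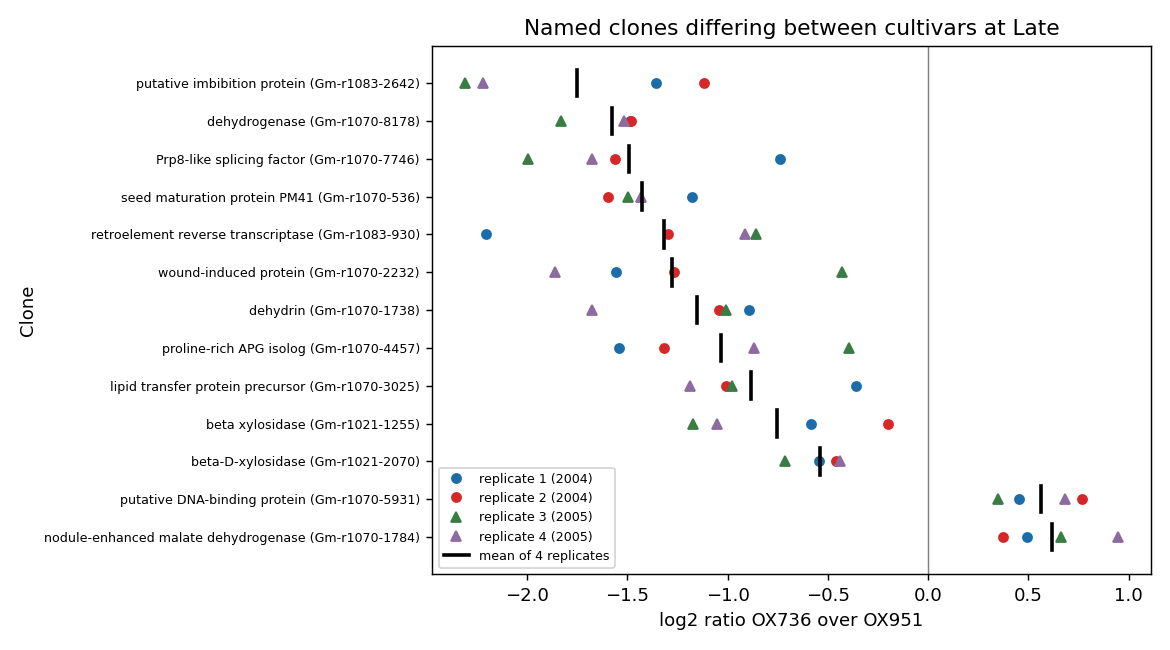
Log2 ratio OX736 over OX951 at Late for the 13 clones named by the rule (y axis: clone and match), with a point per replicate (circles 2004, triangles 2005) and a bar for the mean of 4 replicates. PM41 lies at a mean of -1.43 and the malate dehydrogenase at 0.62.

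At Late 104 clones passed with season as a block, including all 13 named ones. Within 2004 75 passed, 9 of them among the 48, and within 2005 3 passed, 0 of them among the 48. Of the 13 named clones 3 passed within 2004 and 0 within 2005. PM41 had an adjusted p of 0.000638 with the block, a log2 ratio of -1.39 within 2004 (0.0124) and -1.47 within 2005 (0.144). The wound-induced protein had -1.41 within 2004 (0.01) and -1.15 within 2005 (0.275), and the imbibition protein -1.24 (0.0766) and -2.27 (0.0982). Without replicate 1, 2, 3 or 4 the count was 17, 16, 5 or 6, of which 12, 11, 4 and 5 were among the 48, and 2, 3, 3 and 1 of the 13 named clones passed. PM41 passed each time (adjusted p = 0.00786, 0.0366, 0.0107 and 0.0264), and the adjusted p of the other 12 ranged from 0.00591 to 0.281. Plain background subtraction gave 16 clones, with 2 of the 13 named ones among them, and a fit on the Late replicates alone gave 0 by limma (853 at an unadjusted p under 0.05). The main fit shares 1 estimate of the spread over the 3 stages, so its p at Late does not measure the spread of the Late replicates alone. The deposited log2 table, centred on array medians, called 0 higher and 44 lower, against 5 and 43 here.

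Among lists at Late, the seed maturation and dehydrin list was lower in OX736 (median -0.12, 8 of 32 clones above 0, adjusted p = 1.56e-05, or 0.12 with an estimated correlation). Of its 32 clones 3 fell and 29 did not pass, and 12 fell and 1 rose when adjusted over the list alone. Its adjusted p was 2.46e-05 with season as a block, 0.00878 within 2004 (median -0.08) and 0.000759 within 2005 (median -0.24), and the call was lost with OX736 in Cy3 only (median -0.11, adjusted p = 0.310). Beside it, the storage protein list, fixed as the marker of embryo and cotyledon, had a median of -0.08 and an adjusted p of 0.122, and it passed without replicate 2 (median -0.11, adjusted p = 0.00257), with plain background subtraction (0.0251), with all 24 arrays and a correlation of partners (0.0267) and with the Late replicates alone (0.0201). Ribosomal protein clones were lower at Late (median -0.05, 177 of 486 above 0, adjusted p = 0.0126, or 0.575 with an estimated correlation). That list had 0.0128 with season as a block, 0.00888 within 2004 (median -0.09) and 0.429 within 2005 (median -0.03), without replicate 1 or 2 it had 0.136 or 0.117, and with OX736 in Cy3 only 0.589.

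Of the 26 lists that did not pass at Late, those of wall and surface biology lay as follows. The cuticle, wax and cutin list had a median of 0.09 (adjusted p = 0.122, or 0.248 with an estimated correlation), with 2 of 42 clones up when adjusted over the list alone. It passed with plain background subtraction (median 0.16, adjusted p = 0.0359) and within 2004 (median 0.13, 0.0238). Its fatty acid elongase-like clone (Gm-r1021-1743) had 0.53 (adjusted p = 0.0765, or 0.0307 with season as a block). The pectin list had a median of 0.08 (0.511), cellulose and hemicellulose synthesis 0.07 (0.810), expansin, xyloglucan and glucanase 0.02 (0.989), structural wall proteins 0.02 (0.938), lipid transfer 0.02 (0.938), lignin and phenylpropanoids 0.02 (0.938), class III peroxidases 0.03 (0.938) and BURP domain proteins 0.05 (0.938). Flavonoids had 0.01 (0.926), isoflavonoids 0.00 (0.938), chitinases -0.03 (0.926), and vegetative storage proteins with lipoxygenases 0.09 (0.938). Photosynthesis had 0.04 (0.926), histones and cell division -0.01 (0.938), proteases 0.03 (0.810), sugar and starch 0.01 (0.938), defence 0.00 (0.705), heat shock 0.00 (0.938) and aquaporins 0.03 (0.938). ABC transporters had 0.04 (0.926), auxin 0.03 (0.938), gibberellin, abscisic acid and ethylene -0.02 (0.705), redox enzymes -0.01 (0.926) and cytochromes P450 -0.06 (0.511).

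Averaged over the 3 stages, 5 clones differed between the cultivars, and all 5 are named although they were chosen after their values were seen. Flavonol synthase, an enzyme of flavonol synthesis, was higher in OX736 as clone Gm-b10BB-14 (log2 0.60, SE 0.0821, adjusted p = 0.0445) and as clone Gm-r1070-2559 (0.57, SE 0.0809, 0.0462). Clone Gm-r1083-1838, of no descriptive match, was higher by 0.42 (SE 0.0602, 0.0462). PM41 was lower (-0.62, SE 0.0748, 0.0339), as was Gm-r1070-7410, of no descriptive match (-0.49, SE 0.0650, 0.0445). In all 2352 clones had an unadjusted p under 0.05. With season as a block 82 clones passed, the 5 among them at adjusted p of 0.0106, 0.00562, 0.0146, 0.00279 and 0.00888 in the order given. Within 2004 0 passed limma's threshold (1218 at an unadjusted p under 0.05), and within 2005 23 did. Within 2004 and within 2005 PM41 had -0.54 (adjusted p = 0.605) and -0.71 (0.127). Without replicate 1, 2, 3 or 4 the count was 0 each time (2476, 2311, 1187 and 1782 clones at an unadjusted p under 0.05), and PM41 had adjusted p of 0.0954, 0.141, 0.202 and 0.270.

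Whether the cultivar difference itself changed with stage was tested with limma's moderated F test. No clone passed (0 of 18361, 1379 at an unadjusted p under 0.05), so PM41, past the threshold at Late and not at Early or Mid, was not shown to differ between stages. Season as a block gave 3 clones, within 2004 50 did, and within 2005 0 did (865 at an unadjusted p under 0.05). Without replicate 1 the count was 1, and without replicate 2, 3 or 4 it was 0 (1240, 1050 and 1294 at an unadjusted p under 0.05).

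The cultivar difference changed between the growing seasons for 28 clones, 26 of which had a lower OX736 over OX951 ratio in 2005 and 2 a higher one, and all clones named here were chosen after their values were seen. A DnaJ homologue (Gm-r1083-1669), a chaperone partner, had a mean log2 ratio of 0.10 in 2004 and -2.85 in 2005, a change of -2.94 (SE 0.240, n = 6 pairs per season, adjusted p = 0.000182). A type 2C protein phosphatase (Gm-r1021-3430) changed by -2.24 (SE 0.188, 0.000206), a GDSL-motif lipase (Gm-r1070-6965) by -2.05 (SE 0.182, 0.000314), a mitogen-activated protein kinase (Gm-r1083-1279) by -2.0 (SE 0.274, 0.0108) and a bHLH transcription factor (Gm-r1083-1588) by -1.20 (SE 0.112, 0.000417). Others of the 28 had matches outside plants or no descriptive match. Among these were Gm-r1070-2810 (-3.32, a hypothetical Plasmodium protein), Gm-r1021-2377 (-2.94, a human dishevelled homolog) and Gm-r1070-8870 (-2.80, a Caenorhabditis elegans protein). The clones that changed upward, Gm-r1070-3981 (0.89, adjusted p = 0.00290) and Gm-r1070-2948 (0.71, 0.0209), had no descriptive match. Over the 26 clones that fell, the median log2 ratio was 0.12 in 2004 and -1.45 in 2005. Their OX951 levels were higher in 2005 by medians of 1.22, 1.46 and 1.10 at Early, Mid and Late, and their OX736 levels moved by medians of -0.14, -0.35 and -0.70. Not every clone followed these medians. Over all stages the kinase Gm-r1083-1279 moved by 1.83 in OX951 and -0.17 in OX736. Gm-r1070-5565 moved by -0.25 in OX951 and -1.78 in OX736, and Gm-r1083-1322 by 0.08 and -1.02. In all 1875 clones had an unadjusted p under 0.05. Without replicate 1, 2, 3 or 4 the count was 20, 8, 15 or 20, and 16, 8, 13 and 17 of the 28 passed. The deposited log2 table called 10 higher and 34 lower, against 2 and 26 here.

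**Figure D3:**
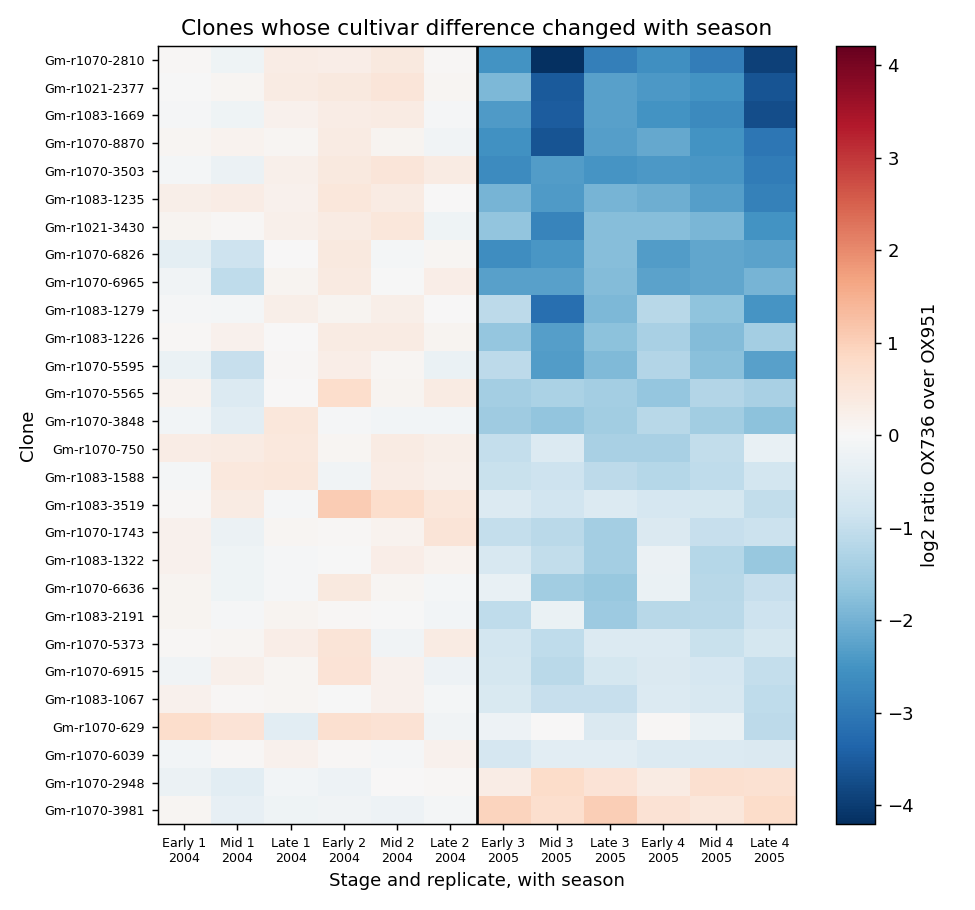
Log2 ratio OX736 over OX951 of the 28 clones whose cultivar difference changed with season (y axis), by stage and replicate (x axis), with colour for the ratio. The 26 falling clones have a median of 0.12 over the 2004 pairs and -1.45 over the 2005 pairs.

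From Early to Mid, averaged over both cultivars, 2134 clones changed, among them risers such as P34, cellulose synthase and a seed coat peroxidase. As Early RNA was of the whole seed and Mid RNA of the seed coat, stage and tissue cannot be told apart in this comparison. Among clones with a descriptive match the largest rise was that of P34 (Gm-r1070-288), a seed vacuole protein and soybean allergen, by 22.2-fold (log2 4.47, SE 0.535, adjusted p = 0.000182), with 6 of 16 Mid channels saturated. A clone matching a vitellogenin, an animal protein, (Gm-r1070-6749) rose 16.2-fold (4.02, SE 0.263, 8.95e-07) and a phosphatidylinositol transfer-like protein (Gm-r1070-7590) 11.3-fold (3.50, SE 0.494, 0.000584). Cellulose synthase (Gm-r1021-1405) rose 9.01-fold (3.17, SE 0.267, 1.18e-05), UDP-glucose dehydrogenase (UGD1, Gm-r1070-5804) 6.96-fold (2.80, SE 0.241, 1.30e-05), and the seed coat peroxidase Ep (Gm-r1070-3409) 5.76-fold (2.53, SE 0.295, 0.000149), with 7 of 16 Mid channels saturated. Among the largest falls were those of an aminoaldehyde dehydrogenase (Gm-r1070-8433, 14.1-fold, log2 -3.81, SE 0.491, 0.000308), a proline-rich protein (Gm-r1021-181, 6.93-fold) and the auxin-related ADR11 (Gm-r1083-3300, 6.89-fold).

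In all, 2134 of 18361 clones changed from Early to Mid, 910 up and 1224 down, and 4818 had an unadjusted p under 0.05. With season as a block 2630 passed, within 2004 743 and within 2005 116. Of the 64 named clones all 64 passed with the block, 55 within 2004 and 23 within 2005. Cellulose synthase rose by 3.26 within 2004 (adjusted p = 0.00689) and by 3.08 within 2005 (0.0239), and P34 rose by 5.14 within 2004 (0.00689) and had 3.81 within 2005 (0.0594). The phosphatidylinositol transfer-like clone had 4.28 (0.00689) and 2.73 (0.123). Without replicate 1, 2, 3 or 4 the count was 753, 1090, 1516 or 1059, and 53, 57, 58 and 60 of the 64 named clones passed, 52 of them every time.

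Among the lists from Early to Mid, the storage protein and embryo list rose (median 0.31, adjusted p = 0.000646, or 0.365 with an estimated correlation). Of its 111 clones 19 rose, 4 fell and 88 did not pass, and 23 rose and 6 fell when adjusted over the list alone. As this list was fixed as the marker of embryo and cotyledon, its rise does not show expression in the seed coat. Whether the Mid samples held embryo RNA was not tested. A glycinin (Gm-r1070-583) rose 8.64-fold (log2 3.11, SE 0.517, 0.00176) and a beta-conglycinin alpha prime subunit (Gm-r1070-1641) 8.13-fold (3.02, SE 0.402, 0.000399), both being storage globulins by their matches, although the platform table gives the latter the symbol P34. Within 2004 and within 2005 the glycinin had 4.22 (0.0170) and 2.0 (0.123), and the conglycinin 3.98 (0.00805) and 2.06 (0.0742). The protease list also rose (median 0.27, adjusted p = 0.00674, or 0.0849 with an estimated correlation), with 15 of 117 clones up and 2 down (16 and 2 adjusted over the list alone), such as an aspartic proteinase (Gm-r1070-3776, 4.71-fold) and a serine carboxypeptidase (Gm-r1070-6606, 3.37-fold). Ribosomal protein clones fell (median -0.54, adjusted p = 1.20e-11, or 0.0849 with an estimated correlation), with 142 of 486 down and 12 up (195 and 21 adjusted over the list alone), the SA protein of the small subunit (Gm-r1021-1332) by 4.86-fold. Histone and cell division clones fell (median -0.22, adjusted p = 0.000646, or 0.292 with an estimated correlation), with 34 of 182 down and 3 up (41 and 3 adjusted over the list alone), a histone H2B (Gm-r1083-2254) by 4.58-fold.

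The adjusted p of these lists with season as a block were 0.000802 for storage proteins, 0.00654 for proteases, 1.34e-11 for ribosomal proteins and 0.000802 for histones. Within 2004 the storage list had a median of 0.38 (3.46e-07), the proteases 0.15 (0.110), the ribosomal list -0.49 (1.28e-11) and the histones -0.16 (0.00479). Within 2005 the medians were 0.25 (0.199), 0.34 (0.00493), -0.62 (1.20e-08) and -0.32 (0.00266). Without replicate 4 the protease list had an adjusted p of 0.0591. The other 24 lists had adjusted p from 0.130 to 0.993. Among their members, lipoxygenases LOX2 (Gm-r1070-1184, 3.85-fold) and LOX3 (Gm-r1070-1485, 3.58-fold), the expansin EXP1 (Gm-r1070-5563, 4.26-fold), a xyloglucan endotransglycosylase (Gm-r1021-375, 4.77-fold) and the seed maturation protein PM34 (Gm-r1070-8705, 3.93-fold) rose. LOX2 was past the threshold without replicates 2, 3 and 4 and not without replicate 1 (adjusted p = 0.0573). Within 2004 and within 2005 LOX2 had log2 changes of 2.99 (0.00899) and 0.90 (0.347), LOX3 2.51 (0.0345) and 1.17 (0.255), and PM34 1.29 (0.0372) and 2.66 (0.0633).

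From Mid to Late, within the seed coat, 1158 clones changed, 649 of them down, including enzymes of anthocyanidin synthesis and lipoxygenase LOX7. Leucoanthocyanidin dioxygenase (Gm-r1070-3124, ANS2), which makes anthocyanidins, fell 17.1-fold (log2 -4.10, SE 0.240, adjusted p = 5.18e-07), and dihydroflavonol reductase (Gm-b10BB-25), a step before it, fell 4.29-fold (-2.10, SE 0.241, 0.000126). A proline-rich protein (Gm-r1021-1480) fell 15-fold (-3.90, SE 0.271, 2.01e-06), the lipoxygenase LOX7 fell 9.91-fold (Gm-r1083-2799) and 9.21-fold (Gm-r1021-2641), and oxygen-evolving enhancer protein 2 (Gm-r1070-4861), a part of photosystem II, fell 8.96-fold (-3.16, SE 0.338, 7.27e-05). Farnesyl pyrophosphate synthase (Gm-r1070-4551), which feeds sterol synthesis, fell at least 6.54-fold (3.70e-06), as it was not well above background in any Late channel. The bound sets its Mid mean against the mean, per array, of the higher of its own level and the lowest level well above background. Among the largest rises were those of the R14 protein (Gm-r1070-3058, 15.8-fold, log2 3.98, SE 0.382, 2.89e-05), a glucan beta-glucosidase (Gm-r1083-2662, 11.5-fold, 3.53, SE 0.269, 3.70e-06), with 12 of 16 Mid channels dim, and a scarecrow-like transcription factor (Gm-r1083-913, 6.49-fold).

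In all, 1158 clones changed from Mid to Late, 509 up and 649 down, and 3838 had an unadjusted p under 0.05. With season as a block 1495 passed, within 2004 868 and within 2005 59. Of the 63 named clones all 63 passed with the block, 47 within 2004 and 20 within 2005. ANS2 fell by 3.84 within 2004 (adjusted p = 0.00216) and by 4.36 within 2005 (0.0132), and R14 rose by 3.26 (0.00422) and 4.70 (0.0132). Without replicate 1, 2, 3 or 4 the count was 426, 290, 746 or 666, and 45, 41, 50 and 45 of the 63 named clones passed, 34 of them every time. Plain background subtraction gave 693 clones.

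**Figure D4:**
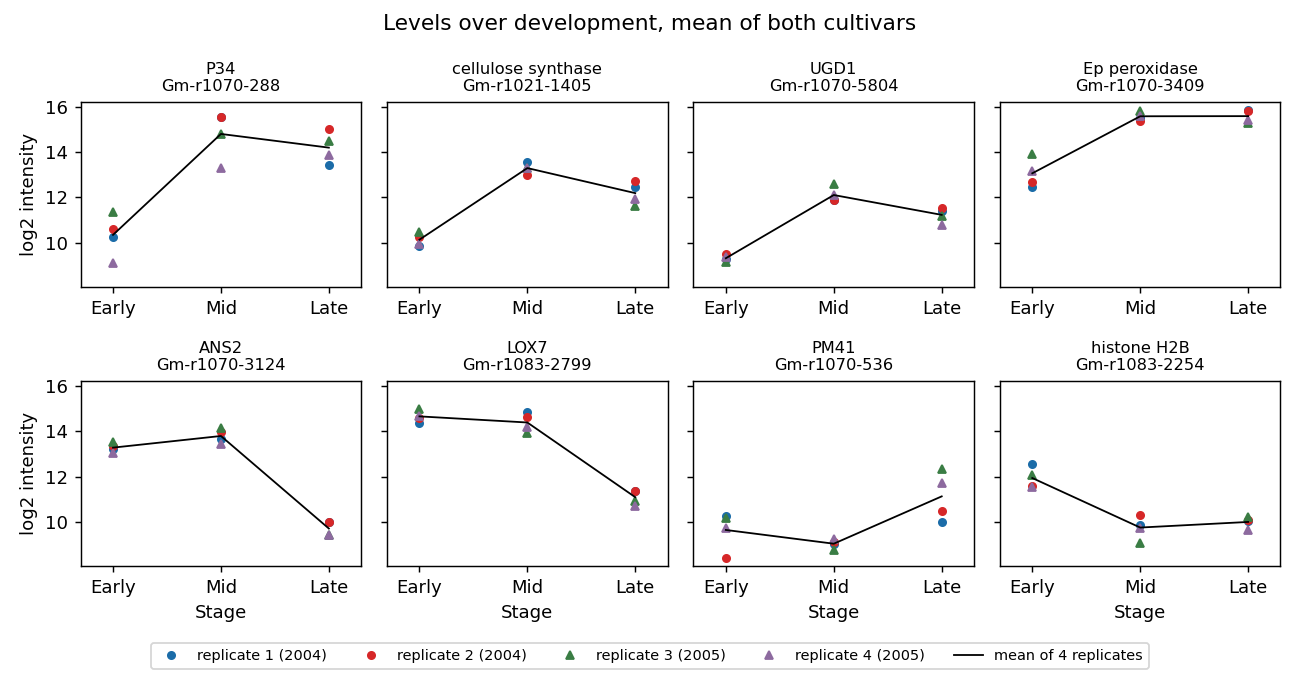
Log2 intensity averaged over both cultivars and dyes (y axis) at Early, Mid and Late (x axis) for 8 clones, with a point per replicate and a line through the means of 4 replicates. Cellulose synthase rose by 3.17 from Early to Mid, and ANS2 fell by 4.10 from Mid to Late.

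By list from Mid to Late, the flavonoid list fell (median -0.31, adjusted p = 9.38e-05, or 0.177 with an estimated correlation), with 10 of 81 clones down and 0 up (16 and 1 adjusted over the list alone). The photosynthesis list fell (median -0.27, adjusted p = 0.000179, or 0.0622 with an estimated correlation), with 20 of 134 down and 5 up (23 and 5 adjusted over the list alone). The vegetative storage protein and lipoxygenase list fell (median -0.20, adjusted p = 0.0135, or 0.297 with an estimated correlation), with 10 of 46 down and 1 up (11 and 1 adjusted over the list alone). Histone and cell division clones fell (median -0.16, adjusted p = 0.0185, or 0.396 with an estimated correlation), with 18 of 182 down and 2 up (22 and 3 adjusted over the list alone). The cellulose and hemicellulose list fell (median -0.23, adjusted p = 0.0295, or 0.396 with an estimated correlation), with 2 of 39 down, cellulose synthase by 2.16-fold and UGD1 by 1.84-fold (4 and 0 adjusted over the list alone). Ribosomal protein clones fell (median -0.15, adjusted p = 0.0334, or 0.511 with an estimated correlation), with 14 of 486 down and 3 up (1 and 0 adjusted over the list alone).

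The adjusted p with season as a block, in that order, were 0.000126, 0.000138, 0.0129, 0.0155, 0.0266 and 0.0266. Within 2004 the medians were -0.26 (0.000167), -0.18 (0.00110), -0.13 (0.000678), -0.14 (0.0102), -0.21 (0.0480) and -0.12 (0.0663), and within 2005 they were -0.20 (0.0215), -0.36 (0.00735), -0.10 (0.242), -0.19 (0.211), -0.25 (0.131) and -0.15 (0.131). Without replicate 1 the lipoxygenase list had an adjusted p of 0.0964 and the seed maturation list passed (median 0.33, adjusted p = 0.0253). Without replicate 2 the histone, cellulose and ribosomal lists had 0.0858, 0.106 and 0.144, and without replicate 4 they had 0.131, 0.0763 and 0.181. Median scaling ended the lipoxygenase, histone, cellulose and ribosomal calls (0.0598, 0.0657, 0.0657 and 0.322), and the pectin list passed (median -0.28, adjusted p = 0.0237). With 1 value per description the lipoxygenase, cellulose and ribosomal calls were lost (0.137, 0.0628 and 0.0973), and the lignin and phenylpropanoid list passed, falling (adjusted p = 0.0129). The cellulose call was also lost with plain background subtraction (0.0739), the OX736 channels alone (0.133) and without Late replicate 4 (0.0544), the ribosomal call without Late replicate 4 (0.0563), and the ribosomal and histone calls with the OX951 channels alone (0.534 and 0.0946), where the seed maturation list passed (0.0431). The other 22 lists had adjusted p from 0.133 to 0.879. In the seed maturation list (median 0.19, adjusted p = 0.145) 7 of 32 clones rose, among them PM41 (4.28-fold, log2 2.10, SE 0.479, 0.0173), which had adjusted p of 0.0277, 0.0365, 0.109 and 0.0987 without replicates 1, 2, 3 and 4, and log2 changes of 1.16 within 2004 (0.269) and 3.03 within 2005 (0.0293). The fold of PM41 rests on low Mid log2 intensities of 8.74 to 9.25, near those of the glucan beta-glucosidase (8.77 to 9.37). The seed coat BURP domain protein SCB1 (Gm-r1070-6036) rose 2.5-fold (1.32, SE 0.352, 0.0376), and cellulose synthase, UGD1 and SCB1 lost the threshold in every fit without 1 replicate (adjusted p = 0.103, 0.0546, 0.0770 and 0.121 for cellulose synthase, 0.116, 0.117, 0.137 and 0.181 for UGD1 and 0.0824, 0.110, 0.136 and 0.107 for SCB1, without replicates 1, 2, 3 and 4). Pectin methylesterase (Gm-r1021-2768, 6.65-fold), a coumarate-CoA ligase of lignin and flavonoid synthesis (4CL4, Gm-r1083-2896, 6.32-fold, -3.30 within 2004 and -2.02 within 2005, adjusted p = 0.00386 and 0.0798) and a cer2-like clone of the wax list (Gm-r1070-1864, 5.79-fold) fell. The folds of 4CL4 and the cer2-like clone rest on low Late log2 intensities, of 8.79 to 9.15 and 8.90 to 9.58.

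None of the list calls above held with an estimated correlation. The list's median, mean and test differed in sign for 10 of 28 lists at Early, 5 at Mid, 7 at Late, 6 from Early to Mid and 4 from Mid to Late, none of them past the threshold. Those included the storage list at Early, the chitinase list at Early and Mid, the heat shock list at Mid and Late, and the class III peroxidase list at Early and in both stage comparisons.

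The self-test arrays, 1 per cultivar with Late RNA of replicate 1 in both dyes, showed the technical spread only. On the cultivar arrays the spread also holds any difference between the plant samples that is not due to cultivar. The SD of log2 ratios across clones was 0.19 for OX951 and 0.16 for OX736, against 0.47 and 0.50 on the cultivar arrays of the same stage and replicate. Over 2-fold apart were 51 and 13 clones on the self-tests and 849 and 950 on the cultivar arrays. The log2 Cy5 over Cy3 values of both self-tests correlated at 0.432 across clones, which are not independent replicates. With 1 array per cultivar there is no replicate check of these values.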

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

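The tests of the season pattern, the signal test of replicate 2 and the embryo test of the maturation clones were chosen after the result was seen. A difference between seasons or stages, or a replicate set apart from the other 3, brought each result here. Of 213 groups of 4 replicates, 11 had such a replicate by Dixon's criterion, and chance gives about 1 in 20.

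The cultivar difference changed with season for 28 clones, and the mean ratio of 26 of them was lower in OX736 in 2005. Their mean log2 ratios in 2004 ran from -0.19 (Gm-r1070-5595) to 0.44 (Gm-r1083-3519). An artefact of the 2005 arrays in only 1 dye orientation would leave the other orientation level. The median 2005 log2 ratio was -1.42 in the weaker orientation and -1.47 in the other, which argues against that for these clones as a set. A dye effect cancels in the mean of both orientations, on which these clones were called, so these values do not test it. Exchanged cultivar labels in 1 season would turn the sign of all clones, and across the other 18333 clones the mean ratios of 2004 and 2005 correlated at 0.127 on average (0.04, 0.14 and 0.19 at Early, Mid and Late). Replicates 1 and 2 of 2004 correlated with each other at only 0.11, 0.22 and -0.08, so the correlation between seasons cannot decide this. For the 26 clones, an exchange would give positive ratios of like size in 2004, where their means were at most 0.44. Other OX951 plant material or growth in 2005 would raise the OX951 channel and leave the OX736 channel within 0.5, and at the median they moved by at least 1.10 and by -0.14, -0.35 and -0.70 at Early, Mid and Late. The Late value lay outside that bound, and some clones did not follow the medians, such as Gm-r1070-5565, which moved by -0.25 in OX951 and -1.78 in OX736. Other OX951 plant material or growth cannot be told apart from the season itself, since each season held its own plants.

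Dye-swapped arrays of replicate 2 did not mirror each other, and at Early their correlation across clones was 0.050, apart from 0.40 to 0.46 in the other replicates. A gene-specific dye effect may hide a shared difference, but with the dye effect of the other replicates taken off, the mean correlation of the 3 pairs of replicate 2 was -0.0006, against 0.60, 0.50 and 0.51 in replicates 1, 3 and 4. Both arrays hybridised in 1 orientation would give a clearly negative value, and the lowest of the 3 was -0.054. Low signal stays open, as the bound for it was set after these values were seen and was not passed: 47.1% to 85.4% of spots reached 1.5 times background in Cy5, over clones at that level in all 4 channels the mean was 0.029 (0.13, -0.16 and 0.11), and at 3 times background 0.093 (0.25, -0.19 and 0.21), although at these levels replicates 1, 3 and 4 had means of 0.68, 0.44 and 0.58, and 0.69, 0.42 and 0.56, and the dimmer pair of Mid replicate 3 had 0.50 and 0.48. A mixed or mislabelled RNA sample was not tested, and the Late array of replicate 2 with OX736 in Cy3 was the 1 of 26 whose slide number in its file differed from its title.

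Of 32 seed maturation and dehydrin clones 3 were lower in OX736 at Late and 29 did not pass, and their list had an adjusted p of 1.56e-05, or an adjusted p of 0.12 with an estimated correlation and 0.310 with OX736 in Cy3 only. Its median in replicate 4 was -0.38, apart from -0.16 to -0.12 in the others. If OX736 seed coats were taken at an earlier point of development, other clones that rise from Mid to Late would be lower too, and their median minus that of falling clones was -0.24 (-0.07, -0.23, -0.32 and -0.35 per replicate). If OX951 coats carried over embryo RNA, storage proteins would be lower in OX736 too, and their median was -0.12 over 4 replicates (-0.23, 0.09, -0.16 and -0.16), against -0.20 for the maturation list, a difference of 0.08 with an SD of 0.16. These and a cultivar difference within the coat cannot be told apart, since the design gives no finer age within a stage.

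Other replicates stood apart as follows. The photosynthesis list at Early had a median log2 ratio of 0.20 in replicate 1, against 0.06 to 0.08 in the others. The dehydrogenase Gm-r1070-8178 at Late had -1.83 in replicate 3, against -1.52 to -1.48. At Mid, replicate 3 had 51.8% of spots well above background, against 92.8% to 96.7%, and log2 intensities of 15.28 for the proline-rich protein Gm-r1021-1480 (14.92 to 14.95 in the others), 13.44 for pectin methylesterase Gm-r1021-2768 (15.03 to 15.31) and 15.21 for PM34, Gm-r1070-8705 (13.32 to 13.64). Mid replicate 4 had 12.62 for the phosphatidylinositol transfer-like clone Gm-r1070-7590 (14.54 to 14.87). Early replicate 1 had 10.63 for the vitellogenin match Gm-r1070-6749 (11.48 to 11.58), and Late replicate 3 had 8.88 for the gibberellin-regulated protein Gm-r1083-1253 (8.68 to 8.70).

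Some cultivar differences had opposite signs in every replicate of 2 stages, and the differences between those pairs of stages were not tested. In all, 87 pairs of stages of named clones and lists were looked at, and how many chance would give was not tested. Malate dehydrogenase Gm-r1070-1784 had a mean log2 ratio of -0.29 at Mid and 0.62 at Late. The DNA-binding protein Gm-r1070-5931 had -0.17 at Early and -0.29 at Mid, against 0.56 at Late. Clone Gm-r1070-8698 had -0.41 at Mid and 0.54 at Late, and clone Gm-r1083-3417 had 0.17 at Early, -0.14 at Mid and 0.67 at Late. The F test over 3 stages gave these 4 clones adjusted p of 0.145, 0.176, 0.145 and 0.415. The ribosomal protein list had a mean median of 0.073 at Mid and -0.055 at Late.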

How the results depend on the processing

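The fits without Mid replicate 3 and without Late replicate 4 were chosen after seeing the data, and the other tests were planned. Causes were not tested unless stated. No deposited log2 value bears on development, as that table holds ratios only. The filter on dim clones left 17493 clones and moved no count by over 1.5 times. It kept clones at 1.5 times background in either channel on a share of 0.5 of the arrays. A clone dim throughout 1 stage could thus stay in, so the filter does not show how far dimness limits the results.

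For 174 results of named clones past the threshold (a clone counts once per comparison), 2779 values under alternatives kept their direction, 2206 of them on the same side of the threshold and 573 not past it. The rule took the largest rises and falls only with the same sign in all 4 replicates, and the alternatives reuse the same arrays. The kept direction was therefore in part set by the choice of clones and is no independent support. Among values named without passing, Gm-r1083-1395 at Early turned to -0.067 within 2004 and Gm-r1070-1 at Mid to 0.022 with OX736 in Cy3 only.

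Counts of clones are given in the order Early, Mid, Late, mean of stages, stage, season, Early to Mid and Mid to Late, where 1, 0, 48, 5, 0, 28, 2134 and 1158 were reported. Leaving out 1 replicate gave Early 0 to 0, Late 5 to 17, mean 0 to 0, stage 0 to 1, season 8 to 20, Early to Mid 753 to 1516 and Mid to Late 290 to 746. The lists past the threshold were then 1 to 2 at Early, 1 to 2 at Late and 3 to 6 from Mid to Late. Fewer samples entered each of these fits.

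Plain background subtraction gave 0 clones at Early, 16 at Late with 4 lists, 0 for the mean and 693 from Mid to Late, and self-test SDs of 0.34 and 0.28. Season as a block gave 5, 16, 104 and 82 clones at Early, Mid, Late and for the mean, and 3 for stage. Within 2004 there were 0 at Early, 75 at Late, 0 for the mean, 50 for stage and 743 from Early to Mid, with 1 list at Mid. Within 2005 there were 2, 1, 3 and 23, and 116 and 59 for development, with 2 lists at Early, 1 at Late and 2 from Mid to Late. The deposited log2 values gave 0 at Early, 0 for the mean and 44 for season, with 2 lists at Early and 0 at Mid. The trended fit gave 0 at Early. Median centring gave 0 at Early, 0 for the mean and an OX951 self-test SD of 0.30.

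With OX736 in Cy5 only there were 26 clones at Late, 130 for the mean and 17 for season, with 2 lists at Early and 1 at Mid. The 2 at Early were the vegetative storage protein and lipoxygenase list and the aquaporin list (adjusted p = 0.0105 each), while the photosynthesis list reported there was lost (0.0858). With OX736 in Cy3 only there were 0, 7, 431 and 1834 at Early, Mid, Late and for the mean, with 0 lists at Late, where the seed maturation and ribosomal calls were lost (adjusted p = 0.310 and 0.589). In such a fit the dye effect does not cancel. All 24 arrays with a correlation of partners (0.247) gave 23, 5, 334, 370, 65 and 120 for the ratio counts up to season. Each stage alone gave 0 at Early and 0 at Late. Median scaling gave 3 lists from Mid to Late, and the OX736 channels alone 1406 and 678 clones for development. An estimated correlation gave 0 lists at Early, 0 at Mid, 0 at Late and 0 in both development comparisons. Without Mid replicate 3 there were 0 at Early, 30 at Late, 0 for the mean, 2188 from Early to Mid and 1326 from Mid to Late, and without Late replicate 4 there were 24 at Late, 2 for the mean, 38 for season and 723 from Mid to Late.

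Beside the zeros, limma's counts at an unadjusted p under 0.05 were, at Early, 585 with plain subtraction, 605 with the deposited values, 797 with the trended fit, 735 with median centring, 1766 with OX736 in Cy3, 1587 with the stage alone and 784 without Mid replicate 3. For the mean they were 2109, 3164 and 2731 with plain subtraction, deposited values and median centring, and 1897 without Mid replicate 3.

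The replicate number as a block gave 2 clones at Early, 4 at Mid, 34 for the mean and 1 for stage, and moved no other count by over 1.5 times. The numbers were not shown to pair the samples. Same-numbered samples of different stages correlated, across clones, at -0.27 to 0.37 in the deviations of their log2 ratios, with 6 of 12 over 0.1. In those of their log2 intensities they correlated at -0.04 to 0.40, with 8 of 12 over 0.1. For ratios the mean was 0.07 for the same number, 0.16 for another number of the same season and -0.12 for the other season. For intensities these means were 0.16, 0.11 and -0.13. The deviations thus went together by season, for which the main fit has no term.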

Other observations

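Gene groups not described above also held clones that changed between stages, and all clones of this paragraph and the next stayed past the threshold without any 1 replicate. From Early to Mid, a sugar transporter (Gm-r1070-6076) rose 4.81-fold (log2 2.27, SE 0.363, n = 4, adjusted p = 0.00137), an ABC transporter (Gm-r1070-5266) 5.59-fold and a thioredoxin family protein (Gm-r1070-5909) 7.25-fold. The isoflavone reductase homolog (Gm-b10BB-33) rose 4.11-fold, the arabinogalactan protein with a fasciclin domain (Gm-r1021-1843) 4.05-fold and the heat shock transcription factor (Gm-r1070-7414) 4.12-fold. An aux/IAA protein (Gm-r1070-3022), a repressor of auxin response, fell 5.39-fold (-2.43, SE 0.344, 0.000604), a cinnamoyl-CoA reductase (Gm-r1070-2653), an enzyme of lignin synthesis, 4.88-fold (-1.41 within 2004, adjusted p = 0.132, and -3.17 within 2005, 0.0239), and a plasma membrane aquaporin (Gm-r1083-2540), a water channel, 4.15-fold. In the gibberellin, abscisic acid and ethylene list 15 of 143 clones rose and 1 fell (median 0.12, adjusted p = 0.209), and in the heat shock list 6 of 148 rose and 19 fell (median -0.15, adjusted p = 0.130).

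From Mid to Late, glutathione S-transferases moved both ways: clone Gm-r1070-929 fell 5.51-fold (log2 -2.46, SE 0.285, adjusted p = 0.000135) and clone Gm-r1070-2682 rose 5.08-fold (2.35, SE 0.275, 0.000141). The gibberellin-regulated protein Gm-r1083-1253 fell at least 3.36-fold (5.99e-05), a heat shock protein (Gm-r1070-5364) 4.87-fold, a peroxidase (Gm-r1070-3221) 5.44-fold, a chitinase (Gm-r1070-3889) 3.63-fold and the aquaporin PIP1 (Gm-r1083-1624) 2.99-fold. In the storage list 1 of 111 clones rose and 9 fell (median -0.03, adjusted p = 0.560).

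The tests on other splits of the samples in this part were all planned, while the season list test, the set of readings behind the development table and the test of exchanged labels were chosen after the data were seen. At a single stage the 8 ways to turn the cultivar labels are too few for a share under 0.05. At Early the real labels gave 1 clone and the others at most 0 (1 of 8 as large), and 1 list against at most 4 (7 of 8). At Mid they gave 0 clones against at most 0 (8 of 8), and 3 lists against at most 2 (1 of 8). At Late they gave 48 clones against at most 5 (1 of 8), and 2 lists against at most 2 (2 of 8).

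Over the 3 stages the 5 clones of the mean were matched or passed in 2 of 100 splits, the real one included. The highest other count, 115, came when only Late replicate 1 was turned and points to a structure of the samples, and its cause was not tested. For stage, the count of 0 was reached in 100 of 100 splits (highest other 3). For season 28 clones stood against at most 2 (1 of 100), so chance was excluded there. From Early to Mid the 2134 clones stood against at most 0 (1 of 35) and from Mid to Late the 1158 clones against at most 49 (1 of 35). Chance was excluded there for labels redrawn freely over all pairs of both stages, a redrawing that did not keep to the seasons. Of the lists, 4 from Early to Mid stood against at most 5 (3 of 35), so chance was not excluded. The 6 lists from Mid to Late stood against at most 4 (1 of 35, the smallest share possible). Redrawn stage labels test whether the 2 stages differ, and not whether a list moved more than other clones. With an estimated correlation 0 of these 6 lists passed, so the splits do not exclude chance for them.

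Between seasons, the ribosomal protein list had a higher OX736 over OX951 ratio in 2005, with a median change of 0.09 and an adjusted p of 0.0254, or 0.553 with an estimated correlation.

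The ratios of the authors' deposited table and the fit used here correlated, across 18352 clones that are not independent replicates, at 0.898, 0.898 and 0.942 for Early, Mid and Late on the log2 scale. All 48 clones past the threshold at Late lay on the same side of 1 there, and PM41 had 0.26. Both sets of ratios come from the same arrays, so this is no independent support. Flavonol synthase clone Gm-b10BB-14 had 1.53, 1.62 and 1.46 at Early, Mid and Late in the authors' deposited table.

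In the authors' deposited development table the OX951 means equalled the mean of the 8 labelled readings within 1 unit for 99.96% to 99.98% of 18201 clones with 1 spot. The OX736 means did so for 50.3% at Early, 49.7% at Mid and 64.0% at Late. Another set of readings matched 99.97%, 99.96% and 99.91%. It exchanged a reading of replicate 1 between Early (Cy3) and Mid (Cy5), and at Late it counted the Cy5 reading of replicate 1 again in place of its Cy3 reading. If the labels of those Early and Mid readings were exchanged, the OX736 over OX951 ratios of these 2 arrays would follow the change from Early to Mid. Their slopes on that change in replicates 2 to 4, across clones, were -0.0091 and -0.055, against 0.63 and -0.69 with the readings exchanged, which argues against exchanged labels. The mean volumes of that table entered no test of expression here, while its match text gave the clone names and the gene lists.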
